A study of Mus musculus with 15 samples.

How the data were processed

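The data were gene expression profiles of 15 mouse livers, 5 groups of 3 mice, from stranded libraries of polyadenylated RNA. Per the submitters' processing notes, the authors aligned reads with Bowtie2 to the mouse build mm9 and estimated expression with RSEM 1.2.23. The deposited expected counts were RSEM estimates per gene, fractional and not scaled between libraries. The deposited TPM and FPKM values were scaled by RSEM within each library by gene length and depth. Each library had 20325 genes, named by symbol, in a single order except in 2 libraries, which were brought into that order. The effective length equalled the gene length to within 0.01, so that no correction for fragment length had entered the TPM. Totals of expected counts per library are given with the samples below. Genomic positions are not reported here, as the reference at hand was of another build. RSEM divides reads among genes of near-identical sequence, so that values of Saa1 and Saa2 and of members of the Mup, Cyp2b, Cyp2c, Cyp3a, Ugt2b, Acnat and Hba families are uncertain.

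The groups were read from the sample labels. The comparisons, tests, alternatives, gene lists and rule for naming genes were fixed before the data were examined, with the exceptions named as added. Expected counts rounded to whole numbers were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and all 15 libraries entered a model with a mean for each of the 5 groups, which left 10 residual degrees of freedom. The biological coefficient of variation was 0.149. Differences were tested by edgeR's quasi-likelihood F test, which is two-sided, and called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors of log2 fold changes were the absolute log2 fold change over the square root of F. CPM values used TMM-scaled totals, and log2 CPM a prior count of 2. The 7 comparisons were ConvR with GF, ConvD with GF and ConvD with ConvR mice on chow, ConvR with GF mice on HF/HS, HF/HS with chow in ConvR and in GF mice, and the interaction of diet with ConvR against GF status.

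Named genes were chosen by a rule with 3 parts. The first took, among called genes with a mean of at least 2 CPM and CPM ranges that did not overlap between the groups, the 8 with the largest log2 fold changes each way, or 5 each way for ConvD against ConvR and the interaction. It passed over predicted genes and small RNA genes. The second took up to 4 members of each described list with the smallest adjusted p, and the third took Cyp7a1, Fasn, Scd1, Cyp3a11, Cd36 and Saa2. A gene named in one comparison could be followed in others, and where a comparison had no call the 3 genes each way with the smallest p were named as not called. Some genes that the rule took are not reported here.

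The 35 gene lists fixed before covered acute phase, interferon response, microbial sensing and MHC class II genes, and immediate early, stress response, circadian clock, NRF2, AHR, and CAR and PXR genes. They covered bile acid synthesis and transport, cholesterol synthesis, fatty acid synthesis and oxidation, lipid droplets, glucose and amino acid metabolism, histone acetylation and methylation enzymes, and male- and female-biased genes. They also covered proliferation and markers of hepatocytes, cholangiocytes, Kupffer cells, monocytes, neutrophils, T and NK cells, B cells, stellate cells, endothelium, red blood cells, adipocytes and exocrine pancreas. Ribosomal proteins were added after the data were seen. Lists were tested by camera in limma 3.58.1 with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison, again with an estimated correlation, and by fry. Counts over the list alone used p adjusted within the list. Beside a list's full counts its median on TPM is given where it lay beyond 1.5 times the main one either way. It was taken on log2(TPM + 1), which shrinks differences of weakly expressed genes, so that a smaller median need not come from scaling. No list kept its camera call with an estimated correlation.

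Each result was recomputed with DESeq2 1.42.0 size factors, with no normalization factors, with no filter and with a stricter filter. It was tested by the DESeq2 Wald test, limma-voom, and limma-trend on log2(deposited TPM + 1). It was also recomputed with the compared groups fitted alone, with the replicate number as a block, with each library left out in turn, and with a fold change of at least 2. Alternatives added later left out ConvR chow 1 and 2, left out these and GF chow 1, used voom with sample weights, or removed from each library a lowess trend (span 0.5) of expression on gene length, estimated over genes with a mean log2 CPM of at least 3. All splits of 6 libraries into groups of 3, and 100 drawn splits where there were more, were tested in the same way. Recovery was tested on simulated data, in which 79 of 100 genes changed by 2-fold and 98 of 100 changed by 4-fold were called between groups of 3, with 4 unchanged genes called. No pair of libraries was a duplicate. Figures were drawn with matplotlib 3.10.9 in python 3.11.15. Deposited FPKM values were not used here.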

Results

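Liver RNA of 15 male C57BL/6J mice, a common inbred laboratory strain, was sequenced at 19 weeks of age, with 3 mice in each of 5 groups. Germ-free (GF) mice carried no living microorganisms, and conventionally raised (ConvR) mice had held a microbiota since birth. Conventionalized (ConvD) mice were GF until 15 weeks of age, when they were gavaged with cecal contents of chow-fed ConvR donors, and were studied 4 weeks later. From 3 weeks of age the mice ate chow or a diet high in fat and sucrose (HF/HS). Fat, carbohydrate and protein gave 23.7%, 53.2% and 23.1% of the energy of chow and 44.6%, 40.6% and 14.8% of that of HF/HS. GF and ConvR mice were studied on both diets and ConvD mice on chow. Mice were housed by group, and GF, ConvR and ConvD mice in different isolators or cages, so that cage and isolator changed together with the group.

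The estimated read counts of replicates 1, 2 and 3 totalled 14737578, 17782515 and 21219381 in GF chow mice and 19113375, 18284245 and 16837867 in ConvR chow mice. They totalled 18296425, 21794811 and 17607907 in ConvD chow mice, 20296412, 19764195 and 17797480 in GF HF/HS mice, and 21331381, 17852369 and 20880135 in ConvR HF/HS mice. Of 20325 listed genes, 4040 had no count in any library and 12368 passed the expression filter. Alb, the gene of serum albumin, took the largest share of each library, 2.86% to 9.50%. Across genes, which are not independent replicates, log2 CPM, read counts scaled by effective library size, correlated at 0.968 to 0.992 between mice of a group and at 0.948 to 0.986 between groups. The first principal component, with 27.3% of the variance, ran from -41.2 to -9.1 in the GF chow and ConvR chow libraries and from 2.1 to 29.9 in the other 9. Levels are given as mean CPM ± SD, the first-named group first, and log2 fold changes ± standard error, with n = 3 mice per group throughout. Adjusted p values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The largest changes named are those among called genes with a mean of at least 2 CPM and no overlap between the 2 groups.

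**Figure D1:**
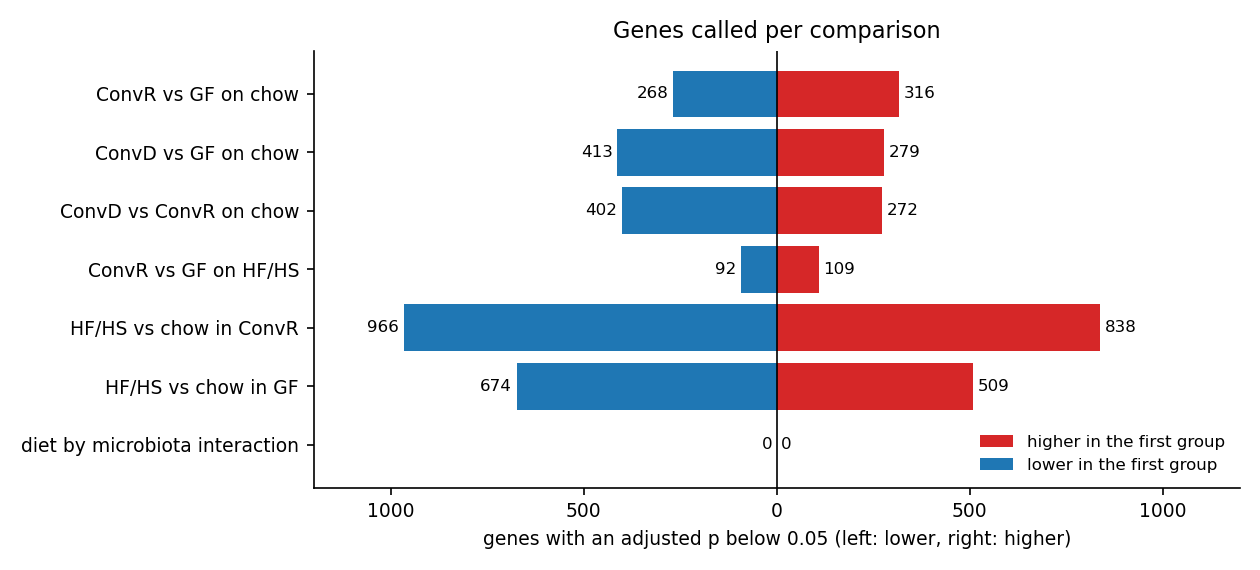
Number of genes called at an adjusted p below 0.05 in each of the 7 comparisons (horizontal axis, lower in the first group to the left in blue and higher to the right in red). The diet comparison in ConvR mice had the most calls, 838 higher and 966 lower, and the interaction had 0.

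On chow, ConvR and GF mice were compared to find the hepatic transcripts that differed with a microbiota present since birth. Acute phase transcripts, which hepatocytes make in response to inflammatory cytokines, were far more abundant in ConvR livers. Saa2, a serum amyloid A gene, stood at 7789.5 ± 6313 CPM against 8.03 ± 4.02 CPM (log2 fold change 9.93 ± 1.09, adjusted p = 0.000742). Lcn2, a lipocalin that binds bacterial siderophores, stood at 867 ± 711 CPM against 2.11 ± 0.673 CPM (log2 fold change 8.66 ± 0.98, adjusted p = 0.000742). Saa1 (7.08 ± 0.88), Saa3 (7.47 ± 0.90) and the acid glycoprotein gene Orm2 (7.12 ± 0.81) were higher by similar log2 fold changes. Saa1 and Saa2 are near-identical genes between which reads could be split wrongly. In the acute phase list, 20 of 28 members were higher, 0 lower and 8 not called, or 26 higher and 0 lower over the list alone. The acute phase median log2 fold change was 2.03 (camera adjusted p = 2.62e-29, adjusted p = 0.378 with an estimated correlation). These transcripts were uneven among the ConvR chow mice: Saa2 reached 9884 CPM in mouse 1, 12790.0 CPM in mouse 2 and 695 CPM in mouse 3, against 4.25 to 53.8 CPM in the 12 libraries of the other groups. Leaving out ConvR chow 1 and 2 gave a list median of 0.06.

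Neutrophil, monocyte and Kupffer cell lists had higher medians in ConvR livers, while T and NK cell (-0.499) and B and plasma cell (-0.365) medians were not called. Prtn3, a neutrophil protease, rose with a log2 fold change of 5.76 ± 0.92 (adjusted p = 0.00935). Among neutrophil markers, 1 of 5 members was higher, 0 lower and 4 not called, or 4 higher and 0 lower over the list alone. The neutrophil median log2 fold change was 1.89 (camera adjusted p = 0.00608, adjusted p = 0.513 with an estimated correlation, median 1.04 on TPM). S100a8, a neutrophil calcium-binding protein, stood at 6.29 ± 4.76 CPM against 1.17 ± 0.725 CPM. Among markers of monocytes and recruited macrophages, 2 of 11 members were higher, 0 lower and 9 not called, or 4 higher and 0 lower over the list alone. The monocyte median log2 fold change was 0.90 (camera adjusted p = 0.000142, adjusted p = 0.378 with an estimated correlation, median 0.28 on TPM). The monocyte chemokine receptor Ccr2 stood at 2.63 ± 1.18 CPM against 0.717 ± 0.207 CPM. Medians of these 2 lists were -0.01 and 0.02 without ConvR chow 1 and 2. Among Kupffer cell markers, 2 of 18 members were higher, 0 lower and 16 not called, or 4 higher and 0 lower over the list alone. The Kupffer cell median log2 fold change was 0.36 (camera adjusted p = 8.84e-05, adjusted p = 0.513 with an estimated correlation, median 0.20 on TPM), and 0.41 without the same mice. Cd163, a hemoglobin scavenger receptor of macrophages, stood at 30.3 ± 9.01 CPM against 14.0 ± 1.62 CPM. Mt2, a metallothionein (5.15 ± 0.98), and Slc13a5, a citrate transporter (3.65 ± 0.71), completed the 8 largest increases on the log2 scale.

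Several immediate early genes, transcription factors and regulators induced within minutes of a stimulus, were lower in ConvR than in GF livers. Egr1 stood at 8.39 ± 2.69 CPM against 155 ± 130.2 CPM (log2 fold change -4.20 ± 0.60, adjusted p = 0.00437), and Fos at 1.55 ± 1.31 CPM against 54.7 ± 65.6 CPM. The nuclear receptor Nr4a1 (-5.32 ± 0.98), Fosb (-6.41 ± 1.08), Atf3 (-3.71 ± 0.84), Fst (-2.94 ± 0.71) and the keratin Krt23 (-2.70 ± 0.47) were also among the 8 largest decreases on the log2 scale. In the immediate early list, 0 of 18 members were higher, 8 lower and 10 not called, or 0 higher and 15 lower over the list alone. The immediate early median log2 fold change was -1.74 (camera adjusted p = 1.35e-11, adjusted p = 0.378 with an estimated correlation). Among the GF chow mice Fos stood at 129 CPM in mouse 1, 28.9 CPM in mouse 2 and 5.95 CPM in mouse 3. The list mean stood at 6.25, 4.50 and 3.45 log2 CPM in these mice and at no more than 3.14 in any library of the other groups. Leaving out GF chow 1 gave a list median of -0.71.

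**Figure D2:**
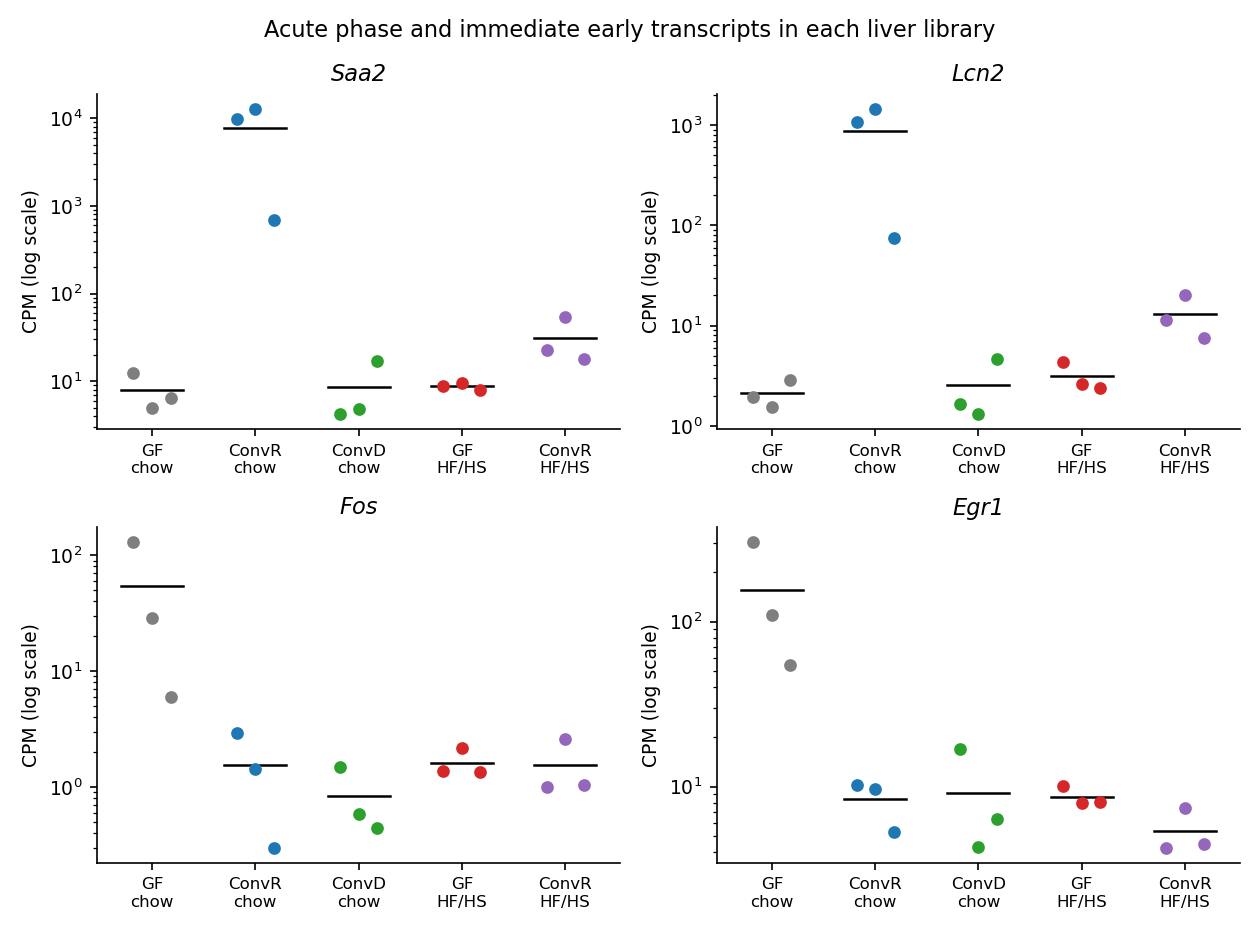
CPM on a log scale of the acute phase transcripts Saa2 and Lcn2 and the immediate early transcripts Fos and Egr1 in the 5 groups, with 1 dot per mouse and a line at the group mean. Saa2 is highest in ConvR chow mice 1 and 2 (9884 and 12790.0 CPM) and Fos in GF chow mouse 1 (129 CPM).

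Some genes of drug, bile acid, sugar and amino acid metabolism also differed on chow. Camera did not call the CAR and PXR drug metabolism (median -0.159) and bile acid synthesis (-0.234) lists. Cyp39a1, an oxysterol 7 alpha-hydroxylase, stood at 10.3 ± 0.822 CPM against 2.35 ± 1.09 CPM (log2 fold change 2.14 ± 0.23, adjusted p = 0.000742). Cyp3a11, a cytochrome P450 induced through the xenobiotic receptor PXR, stood at 2375 ± 1151 CPM against 499 ± 228 CPM (log2 fold change 2.25 ± 0.33, adjusted p = 0.00593). G6pc, the glucose 6-phosphatase of gluconeogenesis, stood at 141 ± 59.9 CPM against 725 ± 478 CPM (log2 fold change -2.36 ± 0.39, adjusted p = 0.0107). Lower log2 fold changes were also found for the insulin receptor substrates Irs2 (-2.06 ± 0.44) and Irs1 (-0.84 ± 0.183). In the glucose metabolism list, 0 of 23 members were higher, 5 lower and 18 not called, or 0 higher and 7 lower over the list alone. The glucose list median log2 fold change was -0.21 (camera adjusted p = 0.00162, adjusted p = 0.378 with an estimated correlation, median -0.35 on TPM), and -0.05 without GF chow 1. In the list of amino acid breakdown and the urea cycle, 0 of 35 members were higher, 8 lower and 27 not called, or 0 higher and 14 lower over the list alone. The amino acid median log2 fold change was -0.35 (camera adjusted p = 1.74e-07, adjusted p = 0.378 with an estimated correlation). Agxt, an aminotransferase of the list, stood at 225 ± 12.4 CPM against 418 ± 148 CPM. In the bile acid transport and FXR list, 0 of 16 members were higher, 3 lower and 13 not called, or 0 higher and 6 lower over the list alone. The bile acid transport median log2 fold change was -0.24 (camera adjusted p = 0.00132, adjusted p = 0.378 with an estimated correlation, median -0.38 on TPM), and -0.10 without ConvR chow 1 and 2. Abcg8, a subunit of the biliary sterol exporter, stood at 55.9 ± 16.3 CPM against 116 ± 18.8 CPM.

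In the list of fatty acid oxidation genes and PPAR alpha targets, 0 of 34 members were higher, 0 lower and 34 not called, or 0 higher and 0 lower over the list alone. The PPAR alpha list median log2 fold change was -0.32 (camera adjusted p = 4.54e-05, adjusted p = 0.513 with an estimated correlation), and -0.08 without ConvR chow 1 and 2. Cyp4a10, a PPAR alpha target, stood at 169 ± 112 CPM against 482 ± 183 CPM (adjusted p = 0.0558). In the NRF2 and conjugation list, 1 of 32 members was higher, 2 lower and 29 not called, or 1 higher and 3 lower over the list alone. The NRF2 list median log2 fold change was -0.28 (camera adjusted p = 0.00248, adjusted p = 0.662 with an estimated correlation, median -0.45 on TPM), and 0.11 without the same mice. Cyp7a1, the rate-limiting enzyme of bile acid synthesis (0.74, adjusted p = 0.153), Scd1, the stearoyl-CoA desaturase (0.90, adjusted p = 0.1797), Fasn, the fatty acid synthase (-0.01, adjusted p = 0.990), and the fatty acid transporter Cd36 (-0.05, adjusted p = 0.935) were not called, with log2 fold changes given first.

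Between ConvR and GF mice on chow 584 of 12368 genes were called, 316 higher and 268 lower. The count was 269 without GF chow 1, 55 without ConvR chow 1, 46 without ConvR chow 2, 1645 without ConvR chow 3 and 10 without ConvR chow 1 and 2 together. Fitted alone, the 6 libraries gave 0 calls, with 1582 genes at an unadjusted p below 0.05, whereas DESeq2 called 1051 and limma-voom 382. Of the calls 54.1% were higher, against 40.6% with no normalization factors and 17.1% on the deposited TPM, where the median log2 fold change of all genes was -0.105. Of the 29 called genes named in the text, 10 kept their call whichever library was left out. Calls ended for Abcg8, Agxt, Atf3, Ccr2, Cd163, Cry2, Dcn, Fos, Fosb, Fst, Irs1, Irs2, Krt23, Lum, Mt2, Nr4a1, S100a8, Setd7 and Slc13a5, 17 without ConvR chow 1, 19 without ConvR chow 2, 8 without GF chow 1, 3 without GF chow 2 and 4 without GF chow 3, with adjusted p up to 0.148, 0.155, 0.0949, 0.0627 and 0.0729 in that order.

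ConvD and GF mice were compared on chow to find the transcripts that differed 4 weeks after an adult GF mouse received a microbiota. Cyp3a11 was the largest increase, at 4992 ± 245 CPM against 499 ± 228 CPM (log2 fold change 3.32 ± 0.35, adjusted p = 0.00182). Scd1 stood at 6533 ± 3084 CPM against 1097 ± 319 CPM (log2 fold change 2.57 ± 0.41, adjusted p = 0.00633). Csad, the cysteine sulfinic acid decarboxylase of taurine synthesis, stood at 349 ± 87.6 CPM against 72.0 ± 24.3 CPM (log2 fold change 2.28 ± 0.35, adjusted p = 0.00633). Cyp39a1 stood at 9.45 ± 0.753 CPM against 2.35 ± 1.09 CPM. The perilipin Plin4 (1.93 ± 0.34), the homeobox gene Lhx6 (1.54 ± 0.27), the galectin Lgals1 (1.22 ± 0.32) and Cyp3a59 (1.19 ± 0.27) completed the 8 largest increases on the log2 scale. In the CAR and PXR list of drug metabolism genes, 3 of 23 members were higher, 0 lower and 20 not called, or 5 higher and 1 lower over the list alone. The CAR and PXR median log2 fold change was 0.177 (camera adjusted p = 0.00634, adjusted p = 0.657 with an estimated correlation, median 0.32 on TPM). Reads of close paralogs in the Cyp2b, Cyp2c and Cyp3a families could be split wrongly. In the lipid droplet list, 2 of 19 members were higher, 0 lower and 17 not called, or 3 higher and 0 lower over the list alone. The lipid droplet median log2 fold change was 0.28 (camera adjusted p = 0.00308, adjusted p = 0.657 with an estimated correlation).

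The median of cholesterol synthesis genes was lower in ConvD than in GF livers. Mvk, the mevalonate kinase, stood at 22.3 ± 1.90 CPM against 47.7 ± 10.9 CPM (log2 fold change -1.09 ± 0.17, adjusted p = 0.00633). Lss, the lanosterol synthase, stood at 44.2 ± 0.610 CPM against 88.5 ± 10.2 CPM and Insig1, a sterol-sensing regulator, at 274 ± 7.35 CPM against 454 ± 23.8 CPM. In that list, 0 of 24 members were higher, 5 lower and 19 not called, or 0 higher and 14 lower over the list alone. The cholesterol median log2 fold change was -0.59 (camera adjusted p = 5.43e-11, adjusted p = 0.657 with an estimated correlation). Among the 8 largest decreases on the log2 scale were Fosb (-7.44 ± 1.18), Fos (-6.01 ± 1.002), the chemokine Cxcl1 (-4.34 ± 1.10), Nr4a1 (-4.25 ± 0.89), Egr1 (-4.09 ± 0.59), Atf3 (-4.06 ± 0.86) and Btg2 (-3.82 ± 0.76). In the immediate early list, 0 of 18 members were higher, 9 lower and 9 not called, or 0 higher and 17 lower over the list alone. The immediate early median log2 fold change was -1.80 (camera adjusted p = 8.58e-14, adjusted p = 0.657 with an estimated correlation), and -0.72 without GF chow 1, the library with the most Fos, at 129 CPM. In the list of unfolded protein and amino acid stress genes, 0 of 21 members were higher, 4 lower and 17 not called, or 1 higher and 8 lower over the list alone. The stress response median log2 fold change was -0.53 (camera adjusted p = 0.00238, adjusted p = 0.657 with an estimated correlation, median -0.28 on TPM), and -0.178 without GF chow 1. Asns, the asparagine synthetase, stood at 1.46 ± 0.649 CPM against 5.02 ± 2.52 CPM.

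Acute phase transcripts were low in both ConvD and GF livers, with Saa2 at 8.73 ± 7.29 CPM against 8.03 ± 4.02 CPM (adjusted p = 0.947). In that list, 0 of 28 members were higher, 0 lower and 28 not called, or 0 higher and 0 lower over the list alone. The acute phase median log2 fold change was -0.09 (camera adjusted p = 0.344, adjusted p = 0.905 with an estimated correlation, median 0.05 on TPM). Among ribosomal protein genes, a list added after the data were seen, 0 of 73 members were higher, 25 lower and 48 not called, or 0 higher and 43 lower over the list alone. The ribosomal protein median log2 fold change was -0.30 (camera adjusted p = 1.60e-20, adjusted p = 0.592 with an estimated correlation, median -0.15 on TPM). Rps21 stood at 57.7 ± 3.86 CPM against 92.3 ± 5.08 CPM. Gene length moved with these groups: the rank correlation of a library's relative expression with gene length ran from -0.451 to 0.058 in the GF chow and ConvR chow libraries and from 0.105 to 0.379 in the other 9. With the length trend of each library removed the ribosomal median was -0.12. Cyp7a1 (0.71, adjusted p = 0.154), Fasn (0.12, adjusted p = 0.803) and Cd36 (0.64, adjusted p = 0.193) were not called.

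Between ConvD and GF mice 692 genes were called, 279 higher and 413 lower. The count was 359 without GF chow 1, 83 without ConvD chow 1, 127 without ConvD chow 2, 142 without ConvD chow 3 and 290 with the length trend removed. DESeq2 called 1157, and a fit of the 6 libraries alone 11. Of the calls 40.3% were higher, against 63.8% with no normalization factors and 88.5% on the deposited TPM. Of the 21 called genes named in the text, 11 kept their call whichever library was left out. Calls ended for Asns, Atf3, Btg2, Cxcl1, Cyp3a59, Insig1, Krt19, Lgals1, Lss and Nr4a1, 10 without ConvD chow 1, 9 without ConvD chow 2, 9 without ConvD chow 3, 5 without GF chow 1, 2 without GF chow 2 and 1 without GF chow 3, with adjusted p up to 0.133, 0.137, 0.0980, 0.160, 0.0646 and 0.0885 in that order.

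**Figure D3:**
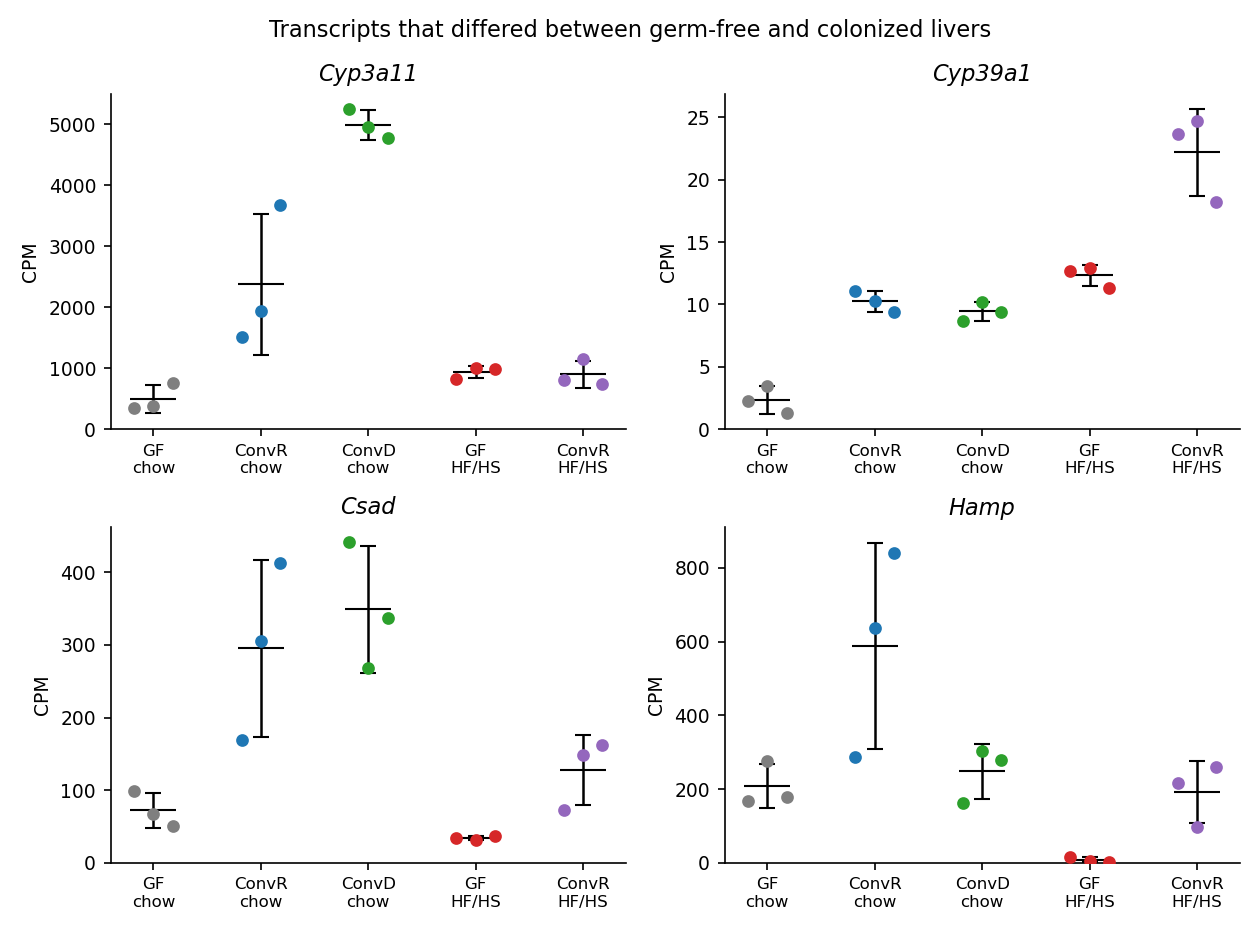
CPM of Cyp3a11, Cyp39a1, Csad and Hamp in the 5 groups, with 1 dot per mouse, a horizontal line at the mean and bars of 1 SD (n = 3 each). Cyp3a11 stands at 4992 ± 245 CPM in ConvD and 499 ± 228 CPM in GF chow livers, and Hamp is lowest in GF HF/HS livers, at 7.56 ± 6.73 CPM.

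Fold changes of ConvD and of ConvR mice against the same GF mice on chow correlated at 0.421 across the 12368 genes (jackknife standard error 0.193 over libraries). Both comparisons called 45 genes higher and 63 lower, and 2 in opposite directions, and independent lists of these sizes would share 7.1 and 8.9. In 20 simulations all libraries, the 3 GF ones included, were drawn anew from a common mean for each gene, so that no group differed. Fold changes against the shared simulated GF group correlated at 0.491 ± 0.031 (SD). No simulated comparison called more than 1 gene, so that their 0 shared calls could not test the observed overlap. The covariance of the fold changes was 0.0898, against 0.0323 in the simulations. As 3 control libraries cannot be split into 2 sets of 2, part of the shared calls may come from the shared controls.

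ConvD and ConvR mice, both colonized and fed chow, were compared directly. Acute phase transcripts were lower in ConvD livers, with Saa2 at 8.73 ± 7.29 CPM against 7789.5 ± 6313 CPM (log2 fold change -9.81 ± 1.08, adjusted p = 0.00106). Lcn2 (-8.44 ± 0.96), Saa1 (-8.66 ± 0.94), Mt2 (-8.82 ± 1.23) and Orm2 (-7.08 ± 0.81) completed the 5 largest decreases on the log2 scale. In the acute phase list, 0 of 28 members were higher, 22 lower and 6 not called, or 0 higher and 27 lower over the list alone. The acute phase median log2 fold change was -2.35 (camera adjusted p = 1.78e-34, adjusted p = 0.316 with an estimated correlation), and -0.35 without ConvR chow 1 and 2. Among neutrophil markers, 0 of 5 members were higher, 3 lower and 2 not called, or 0 higher and 5 lower over the list alone. The neutrophil median log2 fold change was -3.59 (camera adjusted p = 9.39e-05, adjusted p = 0.371 with an estimated correlation, median -1.83 on TPM). In the microbial sensing list, 0 of 19 members were higher, 3 lower and 16 not called, or 1 higher and 6 lower over the list alone. The microbial sensing median log2 fold change was -0.42 (camera adjusted p = 0.00196, adjusted p = 0.382 with an estimated correlation, median -0.08 on TPM). The Toll-like receptor Tlr2 stood at 2.88 ± 0.947 CPM against 16.9 ± 13.1 CPM and Tlr1 at 0.485 ± 0.107 CPM against 1.59 ± 0.232 CPM. Medians of these 2 lists were -0.80 and -0.001 without ConvR chow 1 and 2.

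G6pc was higher in ConvD than in ConvR livers, at 757 ± 124 CPM against 141 ± 59.9 CPM (log2 fold change 2.42 ± 0.40, adjusted p = 0.00930). Hsd17b6, a steroid dehydrogenase, stood at 143 ± 40.03 CPM against 28.1 ± 22.2 CPM (log2 fold change 2.35 ± 0.42, adjusted p = 0.0116). Rgs16 (3.61 ± 0.92), Cabyr (2.42 ± 0.60) and Agxt2l1 (2.03 ± 0.49) completed the 5 largest increases on the log2 scale. In the fatty acid oxidation and PPAR alpha list, 2 of 34 members were higher, 0 lower and 32 not called, or 17 higher and 1 lower over the list alone. The PPAR alpha list median log2 fold change was 0.40 (camera adjusted p = 5.54e-10, adjusted p = 0.371 with an estimated correlation, median 0.64 on TPM). Cpt1a, the carnitine palmitoyltransferase of mitochondrial fatty acid import, stood at 362 ± 17.7 CPM against 252 ± 25.1 CPM. In the NRF2 and conjugation list, 2 of 32 members were higher, 0 lower and 30 not called, or 6 higher and 2 lower over the list alone. The NRF2 list median log2 fold change was 0.38 (camera adjusted p = 2.73e-05, adjusted p = 0.384 with an estimated correlation, median 0.68 on TPM). Ephx1, the epoxide hydrolase, stood at 511 ± 55.4 CPM against 281 ± 124 CPM. Medians of the PPAR alpha and NRF2 lists were 0.13 and 0.04 without ConvR chow 1 and 2. Scd1 was higher (1.68, adjusted p = 0.0307), and Cyp3a11 (1.07, adjusted p = 0.0641), Cd36 (0.69, adjusted p = 0.167), Cyp7a1 (-0.02, adjusted p = 0.972) and Fasn (0.13, adjusted p = 0.790) were not called.

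Between ConvD and ConvR mice 674 genes were called, 272 higher and 402 lower. The count was 106 without ConvR chow 1, 53 without ConvR chow 2, 1592 without ConvR chow 3 and 6 without ConvR chow 1 and 2 together. It was 60 without ConvD chow 1, 16 without ConvD chow 2 and 274 without ConvD chow 3, while DESeq2 called 1124 and a fit of the 6 libraries alone 84. Of the calls 40.4% were higher, against 73.5% of 1090 with no normalization factors and 94.5% of 3727 on the deposited TPM, where the median of all genes was 0.209. Of the 15 called genes named in the text, 4 kept their call whichever library was left out. Calls ended for Agxt2l1, Cabyr, Cpt1a, Ephx1, G6pc, Hsd17b6, Mt2, Rgs16, Scd1, Tlr1 and Tlr2, 7 without ConvD chow 1, 11 without ConvD chow 2, 5 without ConvD chow 3, 7 without ConvR chow 1, 9 without ConvR chow 2 and 1 without ConvR chow 3, with adjusted p up to 0.118, 0.172, 0.0825, 0.120, 0.165 and 0.0507 in that order.

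On the HF/HS diet, ConvR and GF mice were compared to find the transcripts that differed with a microbiota under high fat and sucrose. Hamp, the gene of the iron hormone hepcidin, was the largest increase, at 191 ± 84.8 CPM against 7.56 ± 6.73 CPM (log2 fold change 4.65 ± 0.60, adjusted p = 0.00321). Cidec, a lipid droplet protein, stood at 35.0 ± 31.1 CPM against 1.80 ± 0.722 CPM (log2 fold change 4.26 ± 0.66, adjusted p = 0.00657), and Apoa4, an apolipoprotein, at 2202 ± 1204 CPM against 369.8 ± 62.8 CPM. Ly6d (3.55 ± 0.66), Ntrk2 (2.82 ± 0.45), the monoacylglycerol acyltransferase Mogat1 (2.77 ± 0.46), Hr (2.66 ± 0.39) and Wfdc2 (2.60 ± 0.34) completed the 8 largest increases on the log2 scale. In the lipid droplet list, 5 of 19 members were higher, 0 lower and 14 not called, or 10 higher and 2 lower over the list alone. The lipid droplet median log2 fold change was 0.75 (camera adjusted p = 5.92e-11, adjusted p = 0.132 with an estimated correlation). Its members Plin4 and Plin5 stood at 34.2 ± 17.4 CPM against 6.25 ± 1.87 CPM and 61.1 ± 13.3 CPM against 33.3 ± 2.36 CPM. In the proliferation list, 4 of 20 members were higher, 0 lower and 16 not called, or 14 higher and 0 lower over the list alone. The proliferation median log2 fold change was 1.04 (camera adjusted p = 6.83e-14, adjusted p = 0.132 with an estimated correlation, median 0.60 on TPM). Cdc20, which activates the anaphase-promoting complex, stood at 1.92 ± 0.868 CPM against 0.303 ± 0.0121 CPM and Ccnd1, cyclin D1, at 33.8 ± 9.21 CPM against 16.2 ± 2.08 CPM. Among hepatocyte markers, 0 of 16 members were higher, 1 lower and 15 not called, or 0 higher and 3 lower over the list alone. The hepatocyte list median log2 fold change was -0.21 (camera adjusted p = 0.000738, adjusted p = 0.132 with an estimated correlation, median -0.002 on TPM), and -0.037 with no normalization factors. Ahsg, the gene of fetuin-A, stood at 4000.2 ± 252 CPM against 6791 ± 506 CPM. Among T and NK cell markers, 0 of 10 members were higher, 0 lower and 10 not called, or 0 higher and 2 lower over the list alone. The T and NK cell median log2 fold change was -0.49 (camera adjusted p = 0.0309, adjusted p = 0.499 with an estimated correlation, median -0.14 on TPM). Camera called monocyte (0.581) and Kupffer cell (0.178, 0.368 on TPM) lists higher, at adjusted p of 0.00535 and 0.0343, and 0.521 and 0.735 with an estimated correlation. Cyp39a1 stood at 22.2 ± 3.49 CPM against 12.3 ± 0.854 CPM (log2 fold change 0.85 ± 0.19, adjusted p = 0.0430).

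The median of cholesterol synthesis genes was lower in ConvR than in GF livers on HF/HS. Lss stood at 34.0 ± 10.4 CPM against 59.9 ± 11.8 CPM (log2 fold change -0.82 ± 0.178, adjusted p = 0.0349), and Dhcr7, the last reductase of the pathway, at 62.5 ± 19.9 CPM against 103 ± 14.8 CPM. In that list, 0 of 24 members were higher, 2 lower and 22 not called, or 0 higher and 15 lower over the list alone. The cholesterol median log2 fold change was -0.61 (camera adjusted p = 2.10e-13, adjusted p = 0.282 with an estimated correlation). The zinc importer Slc39a4 stood at 17.9 ± 6.25 CPM against 50.8 ± 4.03 CPM and Enho, the gene of adropin, at 1.42 ± 0.559 CPM against 4.72 ± 0.544 CPM. With Gpx6 (-2.49 ± 0.33), Gpr110 (-2.42 ± 0.43), Cyp2c54 (-1.60 ± 0.31), Susd4 (-1.49 ± 0.22), the elastase Cela1 (-1.36 ± 0.25) and Dsg1c (-1.34 ± 0.27) they were the 8 largest decreases on the log2 scale. Among genes expressed more in male than in female mouse liver, 0 of 27 members were higher, 1 lower and 26 not called, or 0 higher and 6 lower over the list alone. The male-biased median log2 fold change was -0.53 (camera adjusted p = 1.59e-09, adjusted p = 0.472 with an estimated correlation). Among ribosomal protein genes, 0 of 73 members were higher, 9 lower and 64 not called, or 0 higher and 54 lower over the list alone. The ribosomal protein median log2 fold change was -0.28 (camera adjusted p = 3.29e-26, adjusted p = 0.189 with an estimated correlation, median -0.07 on TPM), -0.24 with the length trend removed and -0.107 with no normalization factors. Cd36 (1.17, adjusted p = 0.0542), Cyp3a11 (-0.07, adjusted p = 0.954), Cyp7a1 (-0.25, adjusted p = 0.766), Fasn (-0.01, adjusted p = 0.994), Scd1 (0.09, adjusted p = 0.947) and Saa2 (1.84, adjusted p = 0.286) were not called.

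On HF/HS 201 genes were called between ConvR and GF mice, 109 higher and 92 lower. The count was 75 without GF HF/HS 1, 16 without GF HF/HS 2, 47 without GF HF/HS 3, 126 without ConvR HF/HS 1 and 67 without ConvR HF/HS 2. DESeq2 called 506, and a fit of the 6 libraries alone 453. Of the 201 calls 54.2% were higher, against 93.4% of 767 with no normalization factors and 93.8% of 792 on the deposited TPM, where the median of all genes was 0.164 and 0.157. Of the 24 called genes named in the text, 7 kept their call whichever library was left out. Calls ended for Ahsg, Ccnd1, Cdc20, Cela1, Cidec, Cyp2c54, Cyp39a1, Dhcr7, Dsg1c, Enho, Gpr110, Hr, Lss, Ly6d, Mogat1, Ntrk2 and Plin5, 8 without ConvR HF/HS 1, 9 without ConvR HF/HS 2, 2 without ConvR HF/HS 3, 7 without GF HF/HS 1, 17 without GF HF/HS 2 and 11 without GF HF/HS 3, with adjusted p up to 0.153, 0.169, 0.111, 0.168, 0.168 and 0.170 in that order.

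Fold changes of ConvR against GF mice on chow and on HF/HS, which share no library, correlated at 0.334 across genes (jackknife standard error 0.098), and at 0.125 with no expression filter. Of the genes called in both, 22 were higher on both diets and 21 lower on both, against 2.8 and 2 for independent lists, and 0 were called in opposite directions.

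In ConvR mice, the HF/HS diet was compared with chow. Medians of fatty acid synthesis and lipid droplet genes were higher on HF/HS. Scd1 stood at 16472 ± 8946 CPM against 2045 ± 183 CPM (log2 fold change 3.01 ± 0.41, adjusted p = 0.000582). Elovl5, a fatty acid elongase, stood at 1096 ± 396 CPM against 191 ± 29.2 CPM and Fasn at 692 ± 254 CPM against 350.0 ± 37.4 CPM. In the fatty acid synthesis list, 13 of 23 members were higher, 0 lower and 10 not called, or 13 higher and 0 lower over the list alone. The fatty acid synthesis median log2 fold change was 0.90 (camera adjusted p = 2.69e-11, adjusted p = 0.153 with an estimated correlation). Apoa4 stood at 2202 ± 1204 CPM against 94.1 ± 23.4 CPM (log2 fold change 4.55 ± 0.36, adjusted p = 1.37e-05). In the lipid droplet list, 10 of 19 members were higher, 0 lower and 9 not called, or 14 higher and 0 lower over the list alone. The lipid droplet median log2 fold change was 0.87 (camera adjusted p = 5.70e-13, adjusted p = 0.0864 with an estimated correlation). The adipocyte list was also called (0.581, 1.342 on TPM), and not with an estimated correlation. Cd36 stood at 209 ± 86.1 CPM against 44.9 ± 12.1 CPM. The other large increases on the log2 scale were Cidec (4.30 ± 0.67), Rgs16 (6.32 ± 0.84), Cyp2b9 (8.20 ± 1.78), the glycogen-targeting subunit Ppp1r3g (4.71 ± 1.49), Cidea (4.44 ± 0.89), the hormone gene Fgf21 (4.13 ± 0.56) and Ntrk2 (3.86 ± 0.51).

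Medians of fatty acid oxidation and sugar metabolism genes were also higher on HF/HS in ConvR mice. Cpt1a stood at 502 ± 68.7 CPM against 252 ± 25.1 CPM (log2 fold change 0.99 ± 0.12, adjusted p = 0.000243), and Vnn1, a PPAR alpha target, at 155 ± 43.1 CPM against 34.5 ± 17.9 CPM. In the fatty acid oxidation and PPAR alpha list, 21 of 34 members were higher, 0 lower and 13 not called, or 27 higher and 0 lower over the list alone. The PPAR alpha list median log2 fold change was 0.81 (camera adjusted p = 6.53e-18, adjusted p = 0.103 with an estimated correlation), and 0.43 without ConvR chow 1 and 2. In the glucose list, 13 of 23 members were higher, 0 lower and 10 not called, or 13 higher and 0 lower over the list alone. The glucose list median log2 fold change was 0.59 (camera adjusted p = 3.18e-09, adjusted p = 0.0864 with an estimated correlation, median 0.99 on TPM). Acute phase transcripts were lower on HF/HS: Saa2 (-7.95 ± 0.998), Saa1 (-6.92 ± 0.87), Mt2 (-6.63 ± 1.06), Saa3 (-6.63 ± 0.84), Orm2 (-6.46 ± 0.78) and Lcn2 (-6.06 ± 0.84) were, with the neutrophil protease Prtn3 (-7.24 ± 1.03) and Moxd1 (-8.00 ± 1.46), the 8 largest decreases on the log2 scale. In the acute phase list, 0 of 28 members were higher, 25 lower and 3 not called, or 0 higher and 26 lower over the list alone. The acute phase median log2 fold change was -2.12 (camera adjusted p = 7.19e-21, adjusted p = 0.153 with an estimated correlation, median -1.38 on TPM), and -0.30 without ConvR chow 1 and 2. Among neutrophil markers, 0 of 5 members were higher, 4 lower and 1 not called, or 0 higher and 4 lower over the list alone. The neutrophil median log2 fold change was -3.23 (camera adjusted p = 0.00203, adjusted p = 0.352 with an estimated correlation, median -1.81 on TPM), and -0.946 without the same mice.

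The cholesterol synthesis median and Cyp7a1 were lower on HF/HS in ConvR mice. Mvk stood at 10.4 ± 2.82 CPM against 34.0 ± 1.52 CPM (log2 fold change -1.71 ± 0.179, adjusted p = 0.000113). In the cholesterol synthesis list, 0 of 24 members were higher, 16 lower and 8 not called, or 0 higher and 18 lower over the list alone. The cholesterol median log2 fold change was -0.80 (camera adjusted p = 5.33e-16, adjusted p = 0.144 with an estimated correlation, median -0.43 on TPM). Cyp7a1 stood at 17.6 ± 5.71 CPM against 54.2 ± 18.7 CPM (log2 fold change -1.63 ± 0.30, adjusted p = 0.00329). Cyp7b1, the oxysterol 7 alpha-hydroxylase of the alternative pathway, stood at 118 ± 77.7 CPM against 423 ± 66.7 CPM, whereas Cyp39a1 was higher, at 22.2 ± 3.49 CPM against 10.3 ± 0.822 CPM. In the bile acid synthesis list, 4 of 18 members were higher, 3 lower and 11 not called, or 4 higher and 4 lower over the list alone. The bile acid synthesis median log2 fold change was -0.11 (camera adjusted p = 0.585, adjusted p = 0.9498 with an estimated correlation, median 0.29 on TPM). Cyp3a11 (-1.40, adjusted p = 0.0110) and Cyp2c29 (-1.43, adjusted p = 0.000855) fell and Cyp2c38 (2.15, adjusted p = 0.000477) rose. In the CAR and PXR list, 2 of 23 members were higher, 8 lower and 13 not called, or 2 higher and 8 lower over the list alone. The CAR and PXR median log2 fold change was -0.24 (camera adjusted p = 0.0382, adjusted p = 0.563 with an estimated correlation, median 0.16 on TPM), and -0.51 without ConvR chow 1 and 2. Among AHR targets, 0 of 6 members were higher, 2 lower and 4 not called, or 0 higher and 2 lower over the list alone. The AHR target median log2 fold change was -0.66 (camera adjusted p = 0.00224, adjusted p = 0.0864 with an estimated correlation, median -0.10 on TPM), and -0.31 without ConvR chow 1 and 2. Cyp1a2, a cytochrome P450 of the list, stood at 233 ± 45.5 CPM against 707 ± 93.7 CPM. Among male-biased genes, 0 of 27 members were higher, 10 lower and 17 not called, or 0 higher and 13 lower over the list alone. The male-biased median log2 fold change was -0.87 (camera adjusted p = 2.76e-08, adjusted p = 0.351 with an estimated correlation, median -0.50 on TPM). Among female-biased genes, 7 of 15 members were higher, 2 lower and 6 not called, or 10 higher and 2 lower over the list alone. The female-biased median log2 fold change was 1.62 (camera adjusted p = 8.68e-05, adjusted p = 0.324 with an estimated correlation, median 0.90 on TPM).

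Among ribosomal protein genes, 0 of 73 members were higher, 65 lower and 8 not called, or 0 higher and 70 lower over the list alone. The ribosomal protein median log2 fold change was -0.49 (camera adjusted p = 4.13e-44, adjusted p = 0.0667 with an estimated correlation, median -0.10 on TPM). Rpl12 stood at 101 ± 6.90 CPM against 189 ± 9.33 CPM. The length trend moved with this comparison too, and the list median was -0.30 with the length trend removed. Between the diets in ConvR mice 1804 genes were called, 838 higher and 966 lower. The count was 1118 without ConvR chow 1, 1061 without ConvR chow 2, 991 without ConvR HF/HS 2, 354 without ConvR chow 1 and 2 together and 837 in a fit of the 6 libraries alone. Of the 1804 calls 46.5% were higher, against 84.8% of 3237 with no normalization factors and 95.6% of 6099 on the deposited TPM, where the median of all genes was 0.186 and 0.296. Of the 32 called genes named in the text, 29 kept their call whichever library was left out. Calls ended for Cela1, Fasn and Ppp1r3g, 1 without ConvR chow 1, 2 without ConvR chow 2, 2 without ConvR chow 3, 1 without ConvR HF/HS 1 and 3 without ConvR HF/HS 2, with adjusted p up to 0.120, 0.119, 0.146, 0.0976 and 0.239 in that order.

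**Figure D4:**
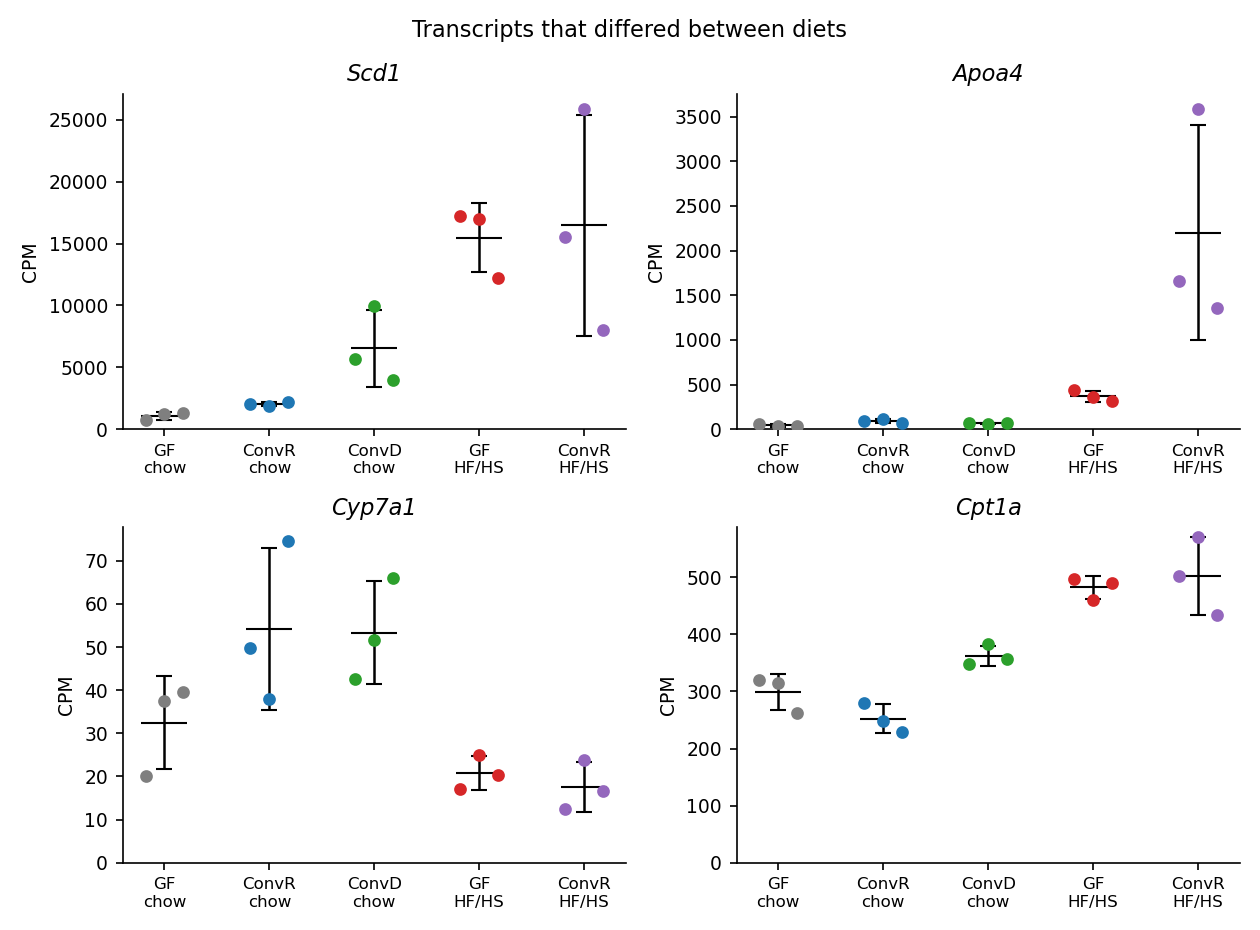
CPM of Scd1, Apoa4, Cyp7a1 and Cpt1a in the 5 groups, with 1 dot per mouse, a horizontal line at the mean and bars of 1 SD (n = 3 each). Scd1 stands at 15466 ± 2798 CPM in GF and 16472 ± 8946 CPM in ConvR livers on HF/HS, against 1097 ± 319 CPM and 2045 ± 183 CPM on chow.

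In GF mice, the HF/HS diet was compared with chow in the absence of a microbiota. Scd1 stood at 15466 ± 2798 CPM against 1097 ± 319 CPM (log2 fold change 3.82 ± 0.43, adjusted p = 0.000617). Pnpla3, a lipase regulated with lipogenesis, stood at 11.3 ± 6.43 CPM against 0.253 ± 0.169 CPM (log2 fold change 5.39 ± 0.69, adjusted p = 0.00109). In the fatty acid synthesis list, 14 of 23 members were higher, 0 lower and 9 not called, or 15 higher and 0 lower over the list alone. The fatty acid synthesis median log2 fold change was 0.98 (camera adjusted p = 4.02e-20, adjusted p = 0.0982 with an estimated correlation). Pklr, the liver pyruvate kinase, stood at 401 ± 44.1 CPM against 101 ± 14.4 CPM and Fasn at 697 ± 127 CPM against 352 ± 42.8 CPM. Apoa4 stood at 369.8 ± 62.8 CPM against 43.8 ± 15.4 CPM. The nicotinic receptor subunit Chrna4 (4.43 ± 0.69), Cyp2b9 (4.17 ± 1.15), Rgs16 (4.05 ± 0.65), the complement factor gene Cfd (3.56 ± 0.73) and the steroid hydroxylase Cyp17a1 (3.18 ± 0.58) completed the 8 largest increases on the log2 scale. Cyp39a1 stood at 12.3 ± 0.854 CPM against 2.35 ± 1.09 CPM (log2 fold change 2.40 ± 0.23, adjusted p = 0.000316). In the glucose list, 7 of 23 members were higher, 0 lower and 16 not called, or 10 higher and 0 lower over the list alone. The glucose list median log2 fold change was 0.29 (camera adjusted p = 4.57e-05, adjusted p = 0.262 with an estimated correlation), and 0.46 without GF chow 1. Khk, the fructokinase, stood at 460.4 ± 26.4 CPM against 279.9 ± 37.6 CPM, and Cd36 at 92.7 ± 12.1 CPM against 46.4 ± 14.9 CPM (adjusted p = 0.0451).

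Hamp was lower on HF/HS in GF mice, at 7.56 ± 6.73 CPM against 208 ± 59.7 CPM (log2 fold change -4.77 ± 0.61, adjusted p = 0.00109). Mvk stood at 16.6 ± 1.36 CPM against 47.7 ± 10.9 CPM, and in the cholesterol synthesis list 0 of 24 members were higher, 7 lower and 17 not called, or 0 higher and 11 lower over the list alone. The cholesterol median log2 fold change was -0.49 (camera adjusted p = 1.29e-08, adjusted p = 0.461 with an estimated correlation). Cyp2b10 (-5.98 ± 1.03), Fosb (-5.84 ± 1.01), Fos (-5.06 ± 0.92), Tchh (-4.89 ± 1.14), Egr1 (-4.15 ± 0.59) and Cyp2c69 (-3.82 ± 0.52) were also among the 8 largest decreases on the log2 scale. In the immediate early list, 0 of 18 members were higher, 9 lower and 9 not called, or 0 higher and 14 lower over the list alone. The immediate early median log2 fold change was -2.17 (camera adjusted p = 2.47e-09, adjusted p = 0.468 with an estimated correlation), and -0.90 without GF chow 1. In the NRF2 and conjugation list, 2 of 32 members were higher, 6 lower and 24 not called, or 2 higher and 10 lower over the list alone. The NRF2 list median log2 fold change was -0.35 (camera adjusted p = 0.000512, adjusted p = 0.720 with an estimated correlation). The glutathione transferase Gstp1 stood at 559 ± 69.8 CPM against 1628 ± 364 CPM. Among male-biased genes, 0 of 27 members were higher, 3 lower and 24 not called, or 0 higher and 8 lower over the list alone. The male-biased median log2 fold change was -0.60 (camera adjusted p = 0.000210, adjusted p = 0.720 with an estimated correlation). Among ribosomal protein genes, 0 of 73 members were higher, 39 lower and 34 not called, or 0 higher and 54 lower over the list alone. The ribosomal protein median log2 fold change was -0.34 (camera adjusted p = 6.33e-25, adjusted p = 0.203 with an estimated correlation), and -0.13 with the length trend removed. Cyp3a11 (0.92, adjusted p = 0.0864), Cyp7a1 (-0.64, adjusted p = 0.193) and Saa2 (0.15, adjusted p = 0.932) were not called.

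Between the diets in GF mice 1183 genes were called, 509 higher and 674 lower. The count was 705 without GF chow 1, 351 without GF HF/HS 1, 344 without GF HF/HS 2, 303 without GF HF/HS 3, 655 with the length trend removed and 259 in a fit of the 6 libraries alone. Of the calls 43.0% were higher, against 64.8% of 623 on the deposited TPM. Of the 25 called genes named in the text, 17 kept their call whichever library was left out. Calls ended for Cd36, Cfd, Cyp2b9, Fabp4, Fasn, Gstp1, Stab2 and Tchh, 3 without GF chow 1, 2 without GF chow 2, 3 without GF chow 3, 5 without GF HF/HS 1, 6 without GF HF/HS 2 and 6 without GF HF/HS 3, with adjusted p up to 0.136, 0.0849, 0.0667, 0.104, 0.0875 and 0.167 in that order.

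Fold changes between the diets in ConvR and GF mice, which share no library, correlated at 0.492 across genes (jackknife standard error 0.072), and 0.203 with no filter. Shared calls were 230 higher on HF/HS and 273 lower, against 34.5 and 52.6 for independent lists, and 2 in opposite directions. Scd1, Apoa4 and Fasn were higher and Mvk lower in both. An unlabelled batch between the diets could add to this.

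**Figure D5:**
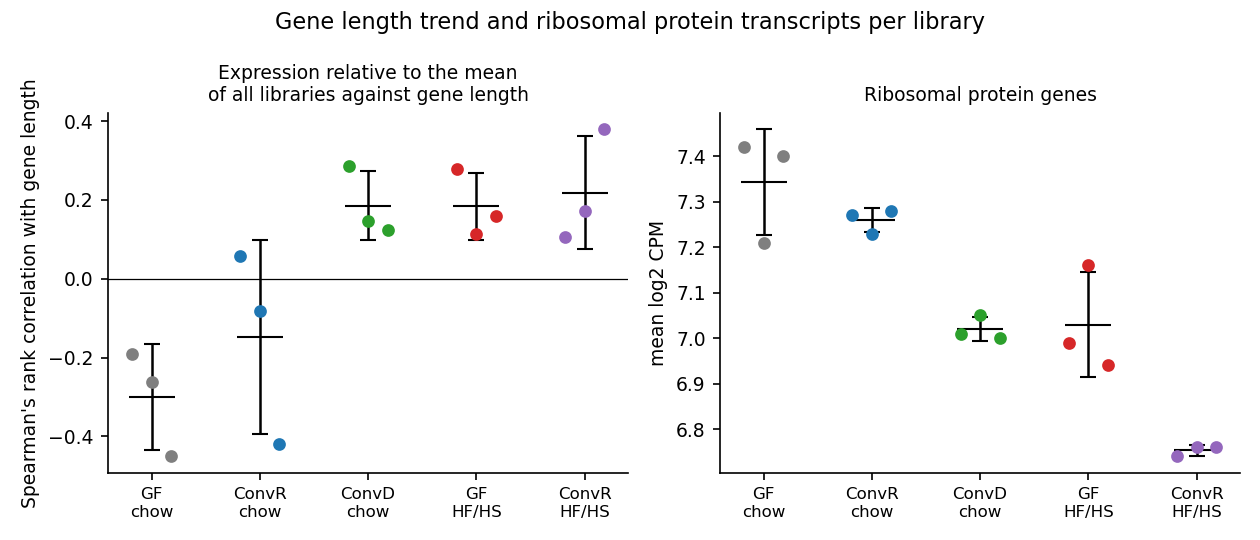
Left, Spearman's rank correlation of each library's expression, relative to the mean of all libraries, with gene length over 7843 genes, and right, the mean log2 CPM of 73 ribosomal protein genes, with 1 dot per mouse, a line at the mean and bars of 1 SD (n = 3 each). This correlation runs from -0.451 to 0.058 in the GF chow and ConvR chow libraries and from 0.105 to 0.379 in the other 9.

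The interaction of diet and microbiota, the question named in the study's title, was tested as the ConvR to GF difference on HF/HS minus that on chow. The genes with the smallest p were Ndrg1 (1.203, adjusted p = 0.0503), the heparan sulfate sulfatase Sulf2 (2.22, adjusted p = 0.0503) and the biliary phospholipid exporter Abcb4 (0.80, adjusted p = 0.0503) among positive differences. Saa2 (-8.10, adjusted p = 0.0503), Orm2 (-6.40, adjusted p = 0.0503) and Fetub, the gene of fetuin-B (-0.85, adjusted p = 0.0503), were those among negative ones, and none of these 6 was called. In the acute phase list, 0 of 28 members were higher, 0 lower and 28 not called, or 1 higher and 24 lower over the list alone. The acute phase median log2 fold change was -1.86 (camera adjusted p = 3.55e-28, adjusted p = 0.290 with an estimated correlation, median -1.198 on TPM), and -0.22 without ConvR chow 1 and 2. In the fatty acid oxidation and PPAR alpha list, 0 of 34 members were higher, 0 lower and 34 not called, or 15 higher and 0 lower over the list alone. The PPAR alpha list median log2 fold change was 0.57 (camera adjusted p = 1.89e-15, adjusted p = 0.290 with an estimated correlation, median 0.89 on TPM), and 0.33 without the same mice. Decr1 (0.66 ± 0.17), Cpt2 (0.47 ± 0.13) and Acadm (0.59 ± 0.183), enzymes of mitochondrial fatty acid oxidation, were among its members of smallest p. In the lipid droplet list, 0 of 19 members were higher, 0 lower and 19 not called, or 5 higher and 0 lower over the list alone. The lipid droplet median log2 fold change was 0.64 (camera adjusted p = 2.27e-07, adjusted p = 0.326 with an estimated correlation), and 0.39 without these mice. In the NRF2 and conjugation list, 0 of 32 members were higher, 0 lower and 32 not called, or 4 higher and 0 lower over the list alone. The NRF2 list median log2 fold change was 0.40 (camera adjusted p = 2.93e-06, adjusted p = 0.630 with an estimated correlation, median 0.72 on TPM), and -0.04 without them. In the immediate early list, 0 of 18 members were higher, 0 lower and 18 not called, or 5 higher and 0 lower over the list alone. The immediate early median log2 fold change was 1.66 (camera adjusted p = 8.62e-10, adjusted p = 0.630 with an estimated correlation), and 0.66 without GF chow 1. Cyp3a11 (-2.32, adjusted p = 0.0967), Cyp7a1 (-0.98, adjusted p = 0.356), Cd36 (1.22, adjusted p = 0.271), Scd1 (-0.81, adjusted p = 0.564) and Fasn (-0.003, adjusted p = 0.998) were not called.

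edgeR called 0 genes for the interaction, with 1572 at an unadjusted p below 0.05, a lowest adjusted p of 0.0503 and 23 genes at an adjusted p below 0.1. limma-voom also called 0, DESeq2 109, and limma on the deposited TPM 1198. The median interaction of all genes was 0.268 on TPM, and 0.221 with no normalization factors, which gave 6 calls. The count was 452 without ConvR chow 3, 21 without ConvR HF/HS 3 and 0 without any other single library. In simulated data, 48 of 100 interactions of 2-fold and 93 of 100 of 4-fold were recovered.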

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

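The tests of colonization, neutrophil RNA, an unlabelled batch, germ-free status and GF chow 1 were chosen after the result was seen. Groups of 3 mice were not examined for single distant samples. The results below are gene lists whose ConvR to GF difference changed with the diet by camera in the interaction, and none kept this with an estimated correlation.

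The acute phase list had an interaction median of -1.86 (adjusted p = 3.55e-28, adjusted p = 0.290 with an estimated correlation), after the high levels in ConvR chow mice, where the mean of the list was 9.89, 10.4 and 7.79 log2 CPM against 6.24 to 7.05 in the other libraries. Colonization by itself is argued against, as the larger of the list medians in ConvD against GF mice on chow and ConvR against GF mice on HF/HS was 0.014. RNA from neutrophils is argued against as the source, as the mean of S100a8 and S100a9, abundant neutrophil transcripts, reached at most 2.17% of Lcn2 in a ConvR chow library. An inflammatory stimulus in the cage or isolator of the ConvR chow mice may account for the pattern and was not tested, as housing cannot be told apart from the group. With ConvR chow 1 and 2 left out the interaction median was -0.22.

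The ribosomal protein list had an interaction median of -0.167 (adjusted p = 1.25e-06, adjusted p = 0.680 with an estimated correlation), which was 0.06 with no normalization factors and 0.19 on the deposited TPM. The list mean of these short genes was lower in ConvD chow and HF/HS libraries. Gene length as the whole cause is argued against between the diets, as the list median lay at percentile 0 of 10000 random lists matched on length and expression in ConvR mice and at percentile 0.02 in GF mice. In ConvD against GF mice the list median lay at percentile 5.14, within the range of matched lists, and may go with length. The percentile was 0 in ConvD against ConvR mice and in ConvR against GF mice on HF/HS, and 99.1 in ConvR against GF mice on chow. An unlabelled library batch stays open: 9 of the 9 ConvD chow and HF/HS libraries had a higher correlation of expression with length than all 6 GF chow and ConvR chow libraries, so that it cannot be told apart from the groups.

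The immediate early list had an interaction median of 1.66 (adjusted p = 8.62e-10, adjusted p = 0.630 with an estimated correlation), after high levels in GF chow mice. Germ-free status by itself is argued against, as the list median in ConvR against GF mice on HF/HS was -0.171. GF chow 1 as the whole cause is argued against, as the list means of GF chow 2 and 3 were 4.50 and 3.45 log2 CPM, the lower one 0.738 above the mean of the 12 libraries of other groups (SD 0.353). Its part stays open: without it the median in ConvR against GF mice on chow was -0.707. The spread was 0.341, the SD on resampling the members of the list, which leaves out the spread among mice. Handling at death, which can induce these genes within minutes, is a biological candidate explanation that was not tested.

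The PPAR alpha, lipid droplet and NRF2 lists had positive interaction medians of 0.568, 0.641 and 0.398. Their camera adjusted p were 1.89e-15, 2.27e-07 and 2.93e-06, and 0.290, 0.326 and 0.630 with an estimated correlation. Without ConvR chow 1 and 2 the medians were 0.33, 0.39 and -0.04. The cholesterol synthesis, female-biased and male-biased lists had medians of -0.276, 1.496 and -0.244, and of 0.04, 0.529 and 0.001 on TPM. Their camera adjusted p were 0.00280, 0.0149 and 0.0181, and 0.705, 0.705 and 0.833 with an estimated correlation. The proliferation and glucose lists had medians of 0.283 and 0.155, and of 0.425 and 0.485 on TPM. Their camera adjusted p were 0.0268 and 0.0351, and both 0.705 with an estimated correlation. The glucose median was 0.07 without GF chow 1 and 0.383 with no normalization factors.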

How the results depend on the processing

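The alternatives that left out ConvR chow 1 and 2, left out these and GF chow 1, removed the length trend or weighted the samples, and the ribosomal protein list, were chosen after seeing the data. The cause was not tested for results that moved, except where fewer libraries or a further threshold entered by construction. In the order ConvR against GF, ConvD against GF and ConvD against ConvR on chow, ConvR against GF on HF/HS, HF/HS against chow in ConvR and in GF mice, and interaction, the counts of called genes were 584, 692, 674, 201, 1804, 1183 and 0. DESeq2 size factors and the stricter filter kept each count within 1.5 times. With no filter the interaction count was 2, and with no normalization factors the counts that moved were ConvD against ConvR, ConvR against GF on HF/HS, the diets in ConvR mice and the interaction, at 1090, 767, 3237 and 6. The DESeq2 Wald test gave 1051, 1157, 1124, 506 and 109 for the first 4 and the interaction, and kept both diet counts within 1.5 times. limma-voom moved the first count, to 382. With sample weights it gave 1325 for ConvR against GF on chow, 2804 for ConvD against ConvR, 1129 for ConvR against GF on HF/HS, 2817 for the diets in ConvR mice and 287 for the interaction. On the deposited TPM the counts other than that of ConvD against GF moved, to 937, 3727, 792, 6099, 623 and 1198. Fitted alone, the groups gave 0, 11, 84, 453, 837 and 259 calls, with fewer residual degrees of freedom, and the interaction gave 0, with 1342 genes at an unadjusted p below 0.05. A fold change of at least 2 left 200, 88, 182, 71, 427 and 193.

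Leaving out each library in turn gave 46 to 1645, 83 to 977, 16 to 1592, 16 to 275, 991 to 2132, 303 to 1402 and 0 to 452 calls in the same order. Without ConvR chow 1 and 2 the count was 10 for ConvR against GF, 6 for ConvD against ConvR and 354 for the diets in ConvR mice, where the remaining ConvR chow library was assumed to vary like the other groups. Without GF chow 1 as well these were 14, 80 and 1129. With the length trend removed ConvD against GF gave 290 and the diets in GF mice 655, and the other counts stayed within 1.5 times. With the replicate number as a replicate block the counts were 402, 489, 476, 143, 1618, 1001 and 0. Replicate numbers did not pair the samples, as 2 of 30 same-numbered pairs correlated above 0.1 after group means were removed (-0.231 to 0.247) and 3 of 15 libraries correlated best with a library of their own number.

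The correlation of fold changes was 0.256 to 0.363 between the 2 diets for ConvR against GF mice with each library left out, and 0.125 with no filter. It was 0.435 to 0.501, and 0.203 with no filter, between ConvR and GF mice for the diets, and 0.309 to 0.542 for ConvD and ConvR against the same GF mice. Genes near 0 counts entered with no filter. Camera called 14, 7, 14, 15, 15, 12 and 10 of 34 fixed lists, and 0 in each comparison with an estimated correlation. The directional fry test called 4, 0, 4, 3, 14, 5 and 0, and the mixed fry test moved the counts of ConvR and ConvD against GF on chow, the diets in GF mice and the interaction, to 22, 18, 19 and 6. Without ConvR chow 1 and 2 camera called 9 lists for ConvR against GF, 7 for ConvD against ConvR and 17 for the interaction. Of 182 pairs of a named gene and a comparison, 146 were called. Under all alternatives 2903 of 3429 values stayed on their side of the threshold, 451 were no longer called and 75 became called. None changed direction while called, and 49 of the 146 calls were kept under each alternative. Values not called in either fit could change sign, as for Cd36 in ConvR against GF mice on chow (-0.245 to 0.27). With 3 mice per group, 48 of 100 simulated 2-fold interactions were recovered. The larger one of Saa2 was not called, so that no size was excluded.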

Other observations

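The splits of the samples were planned, and the test without ConvR chow 1 and 2 used an alternative chosen after the data were seen. Among sinusoidal endothelial markers on HF/HS against chow in GF mice, 5 of 14 members were higher, 0 lower and 9 not called, or 7 higher and 0 lower over the list alone. The endothelial median log2 fold change was 0.39 (camera adjusted p = 4.57e-05, adjusted p = 0.427 with an estimated correlation). Cdh5, the endothelial cadherin, stood at 37.9 ± 3.31 CPM against 25.8 ± 2.32 CPM, and Stab2, a scavenger receptor, at 78.1 ± 5.09 CPM against 56.1 ± 9.20 CPM. Among adipocyte markers in the same comparison, 2 of 3 members were higher, 0 lower and 1 not called, or 2 higher and 0 lower over the list alone. The adipocyte list median log2 fold change was 1.16 (camera adjusted p = 0.0232, adjusted p = 0.371 with an estimated correlation). The fatty acid binding protein Fabp4 stood at 14.9 ± 3.06 CPM against 6.72 ± 2.13 CPM. Among cholangiocyte markers in ConvD against GF mice, 0 of 9 members were higher, 2 lower and 7 not called, or 0 higher and 3 lower over the list alone. The cholangiocyte median log2 fold change was -0.60 (camera adjusted p = 0.0234, adjusted p = 0.657 with an estimated correlation, median -0.30 on TPM). The keratin Krt19 stood at 0.943 ± 0.145 CPM against 2.78 ± 1.99 CPM. Camera also called the endothelial list on HF/HS in ConvR mice (0.318, 0.665 on TPM) and in ConvD against GF mice (0.294), and the Kupffer cell (-0.342, -0.069 on TPM) and monocyte (-0.726, -0.188 on TPM) lists in ConvD against ConvR mice, and no longer with an estimated correlation. Cela1, an elastase of the exocrine pancreas list, stood at 11.6 ± 3.52 CPM against 21.3 ± 9.94 CPM in ConvR mice on HF/HS against chow, and that list, with under 3 measured members, was not tested.

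Lists without a camera call in any comparison, other than bile acid synthesis, are given for ConvR against GF mice on chow. Setd7, a histone methyltransferase, stood at 11.7 ± 2.45 CPM against 6.21 ± 0.112 CPM, and among histone methylation enzymes 1 of 34 members was higher, 0 lower and 33 not called, or 1 higher and 0 lower over the list alone. The histone methylation median log2 fold change was -0.02 (camera adjusted p = 0.719, adjusted p = 0.933 with an estimated correlation, median -0.12 on TPM). Among histone acetylation enzymes, which had a call here, 0 of 30 members were higher, 0 lower and 30 not called, or 0 higher and 2 lower over the list alone. The histone acetylation median log2 fold change was -0.14 (camera adjusted p = 0.0193, adjusted p = 0.378 with an estimated correlation, median -0.25 on TPM). The clock repressor Cry2 stood at 17.3 ± 5.60 CPM against 28.9 ± 2.33 CPM, and among circadian clock genes 0 of 20 members were higher, 1 lower and 19 not called, or 1 higher and 1 lower over the list alone. The circadian clock median log2 fold change was 0.07 (camera adjusted p = 0.765, adjusted p = 0.921 with an estimated correlation, median -0.02 on TPM). The matrix proteoglycans Dcn and Lum stood at 194 ± 16.6 CPM against 135 ± 27.3 CPM and 12.2 ± 1.36 CPM against 5.18 ± 2.92 CPM, and among stellate cell markers 2 of 18 members were higher, 0 lower and 16 not called, or 2 higher and 0 lower over the list alone. The stellate cell median log2 fold change was 0.12 (camera adjusted p = 0.124, adjusted p = 0.662 with an estimated correlation, median -0.02 on TPM). In the interferon response (38 genes), MHC class II (10), B and plasma cell (7) and red blood cell (5) lists, 0 were called. This held over all genes and over the list alone. Their medians were -0.20, -0.03, -0.36 and -0.13, with camera adjusted p of 0.178, 0.399, 0.299 and 0.618.

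A hypothesis was that the positive interaction of fatty acid oxidation and PPAR alpha target genes rests on the 2 ConvR chow libraries with the most acute phase transcripts. Without them the list median was 0.329, against 0.568 with all libraries and a bound of 0.284 set beforehand, with a spread of 0.061, and 31 of 34 members stayed above 0. The values may leave part of the pattern apart from those libraries, and as the median lies within this spread of the bound the hypothesis stays open.

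Other splits of the samples were fitted in the same way. Between groups of 3, the 10 splits are too few for a share under 0.05. In ConvR against GF mice on chow 2 of 10 splits gave as many genes as the real 584, with 815 in the highest other, which set ConvR chow 1 and 2 and GF chow 1 against the other 3. The real split alone, 1 of 10, reached its count in ConvD against GF mice (692, highest other 1), ConvD against ConvR mice (674, highest other 2) and ConvR against GF mice on HF/HS (201, highest other 0). The same held between the diets in ConvR mice (1804, highest other 9) and in GF mice (1183, highest other 0). For the interaction the real count was 0, which any split must reach, so that the 100 splits could not test it, and the highest other gave 753. The correlation of fold changes of ConvR against GF mice on the 2 diets, 0.334, was reached by 1 of 100 splits, the real one. The farthest other from 0 was -0.322, a margin small beside the jackknife standard error of 0.098. Chance is argued against but was not excluded. That of the diets in ConvR and GF mice, 0.492, was also reached by 1 of 100 (-0.337), which argues against chance but not a batch. For ConvD and ConvR mice against the same GF mice 62 of 100 splits gave at least 0.421, with 0.865 in the highest other, so that chance and the shared controls were not excluded.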
